A study of Drosophila melanogaster with 4 samples.

How the data were processed

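Chromatin from nuclei of adult *Drosophila melanogaster* heads was immunoprecipitated with an antibody against H3K79me3 and sequenced, with input chromatin as background. The series holds 2 ChIP libraries and 2 input libraries, and the labels give each input as the background of the ChIP library of the same number. Heads were sieved from adults and the chromatin was crosslinked with formaldehyde and sonicated, per the labels' protocols. The deposited files are 3 lists of regions of significant enrichment, per the file headers and feature types: 1 per ChIP library and 1 for the replicate set. The coordinates are on FlyBase release 5, per the file headers. Bowtie 0.12.7 is named in the submitters' processing notes, without its role. The region caller, its threshold and the way the replicates were put together are not given in the sources used here.

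Each region has a start, an end and a score given by the authors, whose definition and scale are not given in the sources used here. The authors' score was used as deposited, to rank or filter clusters within a list and to compare paired clusters. The lists hold no read counts, so the depth of the libraries is unknown and no interval that needs it is given. Wilson 95% intervals of shares of clusters cover counting error only, and neighbouring clusters are not independent. The input libraries were not analysed here as lists of their own.

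All sequence lengths came from the file headers. For each list, clusters, covered length, widths, scores and gaps were computed, and the mean and SD over both replicates are given. Replicate lists were compared by the Jaccard index of covered bases and by the share of clusters overlapped by at least 1 base. The reference was 100000 random rotations of replicate 2 within each arm in bins of 100 bases, tested one-sided. With an overlap of at least 50% of both clusters, 1000 rotations were drawn. Scores were compared over clusters paired by their largest mutual overlap. X was compared with 2L, 2R, 3L and 3R, and chromosome 4 with all 5 large arms, by the covered percentage. The two-sided exact test went over all rotations of the joined map in bins of 1 kb. Neighbouring rotations overlap almost entirely, so for a block as long as a large arm they amount to few independent positions. The 2 Mb next to the centromere were compared with the rest of each arm by 100000 rotations within arms, two-sided. Next to the centromere means the end of the arm sequence on that side, by the usual orientation of the arms. Heterochromatic sequences such as 3RHet are separate from the arms, so the distance to the centromere itself is unknown. The bases of the combined list were divided by whether both, 1 or neither replicate list covered them.

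Alternatives fixed before the data were examined were clusters at or above the median score of their list, clusters closer than 1000 bases joined, other overlap rules, other bins, 1 Mb or 4 Mb next to the centromere, clusters per Mb, the large arms only, the combined list, and each replicate left out. Leaving out the 2 Mb next to the centromere in the comparisons of X and chromosome 4 was added after the data had been seen, as were rotations of the order of clusters along the arms and the rotation values by class of score and width. Regions named in the text follow a rule fixed before the data were examined: the 10 highest scores and the 5 longest clusters of the combined list, and the 5 longest stretches of the large arms with no cluster in any list.

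Comparisons with transcription start sites and with 18 fixed gene lists were planned only for an annotation of release 5. The gene table used here is of release 6, coordinates were not converted, and these comparisons were not run.

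The overlap and X tests were tested on simulated data, in 100 simulations of 6180 randomly placed clusters each. The overlap test gave p under 0.05 in 1% of pairs of unrelated maps and in 100% of pairs that kept 70% of the clusters. The X test did so in 0% of maps with no difference and in 100% of maps with 30% of X clusters removed. In these maps all arms were first thinned to the covered share of X, which held the difference small by construction. The 0% is therefore not an estimate of the false-positive rate. Real clusters are grouped along the arms, which these maps are not, so these shares do not give the power of the X test on real maps. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.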

Results

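Trimethylation of lysine 79 of histone H3 (H3K79me3), a mark set by the Dot1 methyltransferase (grappa in flies) and commonly described over transcribed genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei from the heads of wild-type Oregon-R adults of *Drosophila melanogaster*. The series holds 2 ChIP libraries and 2 input libraries. The authors used each input as the background of the ChIP library of the same number, per the labels. The data are 3 lists of enriched regions, here called clusters, on FlyBase release 5: 1 list per ChIP library and 1 list for the replicate set, here called the combined list. Each cluster has a start, an end and the authors' score, whose scale is not given in the sources used here. The score is therefore used only to rank clusters within a list or to compare it between lists cluster by cluster. The read depth of the libraries is unknown from these files, so clusters near the authors' threshold cannot be given a counting interval. The labels do not say whether the libraries came from separate collections of flies. The spread between them may therefore be technical, and the p-values below come from rotating cluster maps along the genome, not from a test across samples.

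The question asked first was how much of the genome was called enriched for the mark in head nuclei. H3K79me3 clusters covered 27.9% of the 5 large chromosome arms (X, 2L, 2R, 3L and 3R) in replicate 1 and 28.4% in replicate 2, a mean of 28.2% ± 0.39 (SD, n = 2). The combined list covered 34.3% of them. These shares depend on the authors' caller and threshold, which are not given, and the SD does not cover that. Most clusters were a few kilobases wide: the median width was 3486.5 bases in replicate 1 and 3389.5 bases in replicate 2, and the interquartile range ran from 2120.75 to 6239 bases in replicate 1. Clusters wider than 20 kb numbered 167 in replicate 1 and 169 in replicate 2, or 2.64% ± 0.038 of clusters (SD, n = 2), and held 15.4% ± 0.25 of the covered bases (SD, n = 2). Replicate 1 had 6264 clusters over 33.4 Mb and replicate 2 had 6470 clusters over 34.1 Mb. Neighbouring clusters were often close: 28.6% of the gaps in replicate 1 and 28.5% of those in replicate 2 were shorter than 1 kb.

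Wider clusters also had higher scores. Across clusters, which are not independent replicates, Spearman's rho between width and score was 0.75 in replicate 1 and 0.75 in replicate 2. In replicate 1 the median score rose from 0.591 in the lowest quartile group of widths, with a median width of 1659 bases, to 1.14 in the highest, with a median width of 9506 bases. In replicate 2 the corresponding medians were 0.539 and 1.10. Among clusters at or above the median score, the mean rho of both lists was 0.32. This filter narrows the range of scores, which by itself can lower rho.

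The second comparison asked whether both libraries marked the same places. They did so for most of the covered sequence: 30.7 Mb was covered in both, which is 83.6% of the bases covered in either (the Jaccard index). Rotating the map of replicate 2 within each arm gave a mean of 16.4% and an upper bound of its central 95% range of 17.4%, and none of 100000 rotations reached the observed value (one-sided permutation test, p = 1e-05, the smallest they can give). Of the 6264 clusters of replicate 1, 5749 (91.8%, 95% Wilson interval 91.1 to 92.4) overlapped a cluster of replicate 2 by at least 1 base, against 42.1% after rotation (one-sided permutation test, p = 1e-05). Of the 6470 clusters of replicate 2, 5736 (88.7%, interval 87.9 to 89.4) overlapped one of replicate 1, against 41.2% after rotation (p = 1e-05, same permutation test). These intervals cover counting error only.

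Clusters seen in a single library were short and low in score. The 515 clusters found only in replicate 1 had a median width of 1569 bases, against 3817 bases for its shared clusters, and a median score at the 18.2 percentile of its list. The 734 clusters found only in replicate 2 had a median width of 1617 bases, against 3857.5 bases for shared ones, and a median score at the 18.9 percentile. All clusters wider than 20 kb, 167 in replicate 1 and 169 in replicate 2, overlapped one of the other library, against 69.6% and 68.7% after rotation (one-sided permutation p = 1e-05 each). Among the 10% of clusters with the highest scores, all 627 of replicate 1 and all 647 of replicate 2 were shared. Among the lowest 10%, 76.2% of replicate 1 clusters (interval 72.8 to 79.4) and 70.5% of replicate 2 clusters (interval 66.9 to 73.9) were shared. Wider clusters overlap more by chance: rotation gave 49.2% and 48.0% in the highest 10% by score, and 34.8% and 34.5% in the lowest 10%. Score and width are linked, and within the lowest quartile group of widths sharing was not higher at higher scores. There, 74.1% of replicate 1 clusters below the median score of the group were shared and 69.5% of those at or above it, and in replicate 2 66.9% and 55.4%. These class values were computed after the data had been seen.

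**Figure D1:**
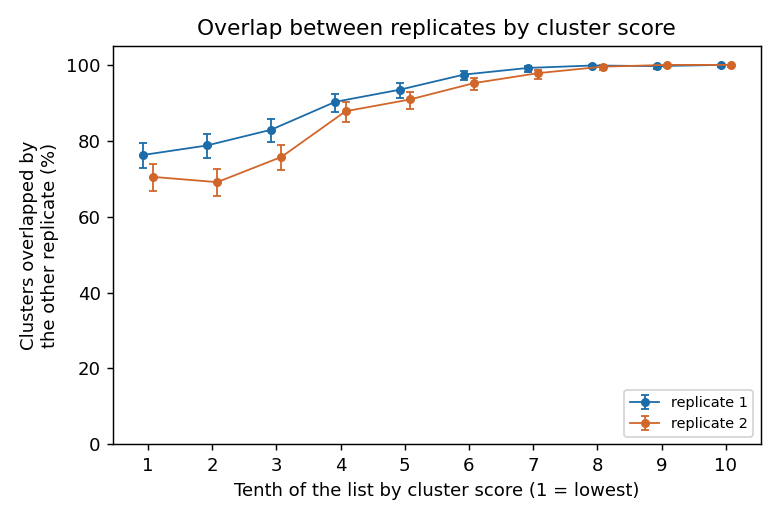
Percentage of the clusters of each replicate that overlap a cluster of the other replicate by at least 1 base, in 10 groups of equal size ranked by score (group 1 is the lowest). Points are percentages, bars are 95% Wilson intervals; sharing is 76.2% and 70.5% in the lowest group and 100% in the highest group of both lists.

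Where both libraries had a cluster, its borders and its score were close. Among 5233 clusters paired by their largest mutual overlap, the start differed by a median of 159 bases and the end by a median of 156 bases. Scores ranked alike across these pairs, with Spearman's rho of 0.92 and Pearson's r of 0.93 across clusters. The score was higher in replicate 1 for 63.9% of pairs, and the median difference, replicate 2 minus replicate 1, was -0.037, against an SD of the differences of 0.114.

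The coverage profile along the arms was also alike in both libraries. In 117 full windows of 1 Mb, the covered share ranged from 1.47% to 54.6% as a mean of the replicates, and the replicates differed by at most 3.03 percentage points in any window. The shorter last piece of each arm was left out. The 3 most covered windows were 5 to 6 Mb on 3R (54.3% in replicate 1 and 54.8% in replicate 2), 1 to 2 Mb on X (44.9% and 46.2%) and 6 to 7 Mb on 2R (43.8% and 44.3%). The 3 least covered were 23 to 24 Mb on 3L (1.72% and 1.23%), 22 to 23 Mb on 2L (3.90% and 3.69%) and 0 to 1 Mb on 2R (4.58% and 4.54%), all on the centromere side of their arms.

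**Figure D2:**
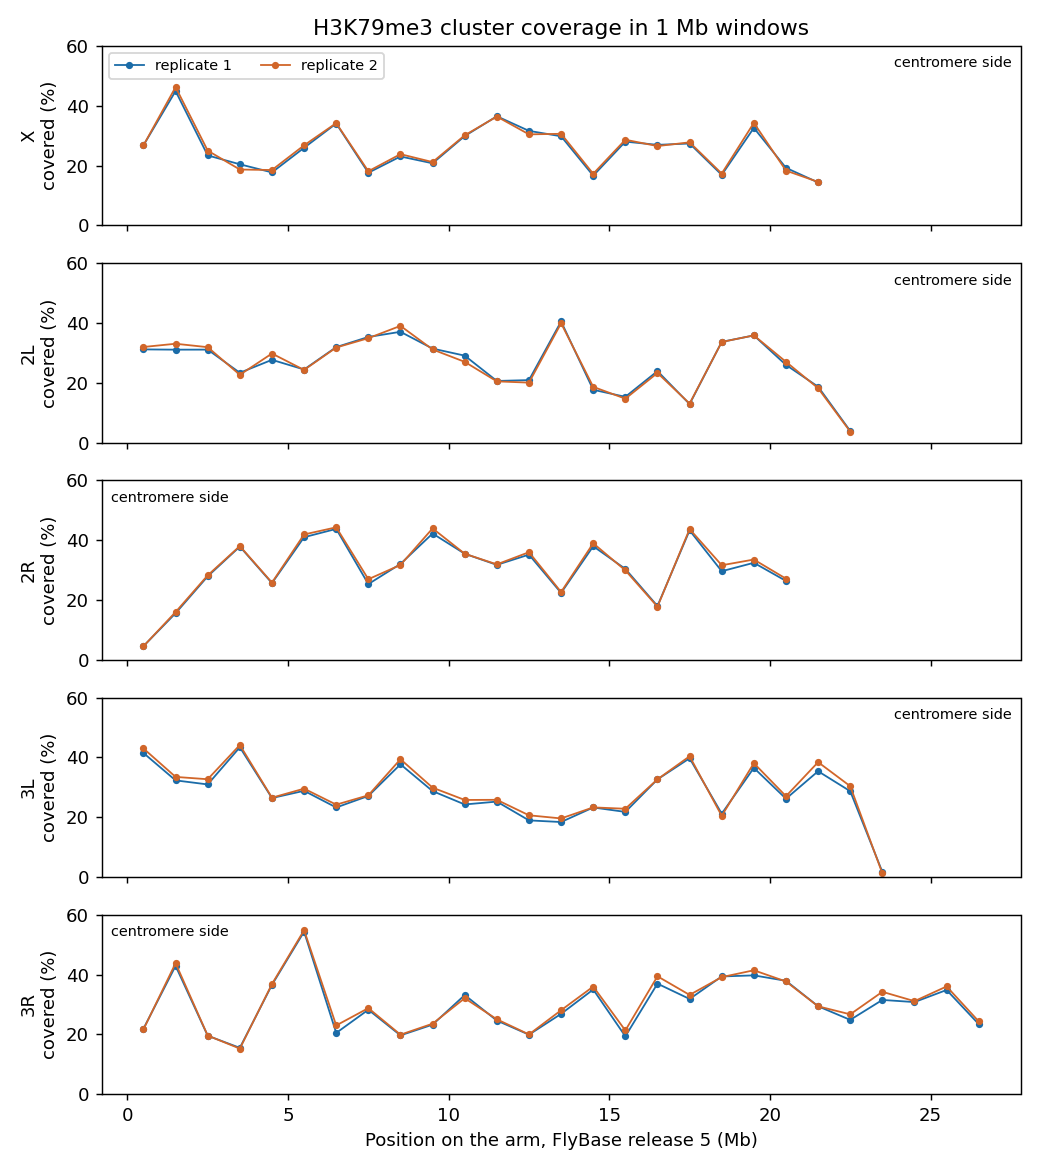
Percentage of each 1 Mb window covered by H3K79me3 clusters (vertical axis) along the 5 large arms (horizontal axis, Mb on FlyBase release 5) in replicate 1 (blue) and replicate 2 (orange); the centromere side of each arm is marked. The shorter last piece of each arm is left out. The replicates differ by at most 3.03 percentage points, and among these windows coverage is lowest at 23 to 24 Mb on 3L, with 1.47% (mean of both).

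The third comparison set the arms against each other, beginning with X, which in flies is present once in males and is subject to dosage compensation. The covered share of X was lower than that of the large autosomal arms in both libraries, by an amount that did not pass the rotation test. X is a large part of the joined map, so the rotations overlap heavily and the test could miss a real difference. Clusters covered 25.2% of X and 28.5% of the autosomal arms in replicate 1, a difference of -3.25 percentage points (two-sided exact test over all 119032 rotations of the map in 1 kb bins, p = 0.183). In replicate 2 the shares were 25.6% and 29.1%, a difference of -3.53 points (same exact rotation test, p = 0.199). X had 57.6 ± 2.0 clusters per Mb against 51.7 ± 1.1 on the autosomal arms (SD, n = 2), so the sign turned when clusters were counted instead of bases, again without passing the test (exact rotation p = 0.219 for the mean of both). The direction also did not hold among clusters at or above the median score: the difference was -1.11 points in replicate 1 (exact rotation p = 0.717), 0.179 points in replicate 2 (exact rotation p = 0.973) and 0.290 points in the combined list (exact rotation p = 0.943). With all clusters of the combined list it was -1.67 points (exact rotation p = 0.659). With 2 pairs, an exact test across the libraries cannot give a p below 0.5, and none was run.

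Long domains were a smaller share of the clusters on X. Of 1260 X clusters in replicate 1, 12 were wider than 20 kb (0.952%), against 155 of 4920 on the autosomal arms (3.15%). In replicate 2 the numbers were 10 of 1324 (0.755%) and 159 of 5073 (3.13%). Rotating the order of the clusters along the arms gave exact two-sided p values of 0.00793 and 0.0061, a test chosen after the widths had been seen. The median width was 3184.5 ± 106 bases on X and 3576 ± 61 bases on the autosomal arms (SD, n = 2). X clusters nevertheless ranked higher by score: their mean score percentile was 55.8 against 48.5 in replicate 1 and 59.4 against 47.6 in replicate 2 (exact two-sided rotation of cluster order, p = 0.00356 and p = 0.000156, the latter the smallest it can give). This test, too, was chosen after the data had been seen. Among the top 10% by score were 120 of 1260 X clusters and 498 of 4920 autosomal clusters in replicate 1 (exact rotation p = 0.786), and 159 of 1324 and 481 of 5073 in replicate 2 (exact rotation p = 0.233).

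Among the other large arms, coverage was highest on 2R (30.5% ± 0.38, SD, n = 2) and 3R (30.3% ± 0.55), and lower on 3L (27.9% ± 0.66) and 2L (26.3% ± 0.079). No large arm passed the exact rotation test against the remaining 4 in any of the 3 lists, where p ran from 0.183 to 0.996. With a whole arm as the tested block the rotations overlap heavily, so the test does not show that the arms are alike.

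Chromosome 4, a small and largely heterochromatic chromosome, had a lower covered share than the large arms in both libraries, without passing the test. Clusters covered 11.8% of it in replicate 1 and 11.2% in replicate 2, a mean of 11.5% ± 0.41, against 28.2% ± 0.39 of the large arms (SD, n = 2). Its 46 ± 1.4 clusters were short, with a median width of 2886.5 ± 128 bases, and none was wider than 20 kb. The difference was -16.1 points in replicate 1 and -17.2 points in replicate 2. It did not pass the exact two-sided rotation test in either (p = 0.06 and p = 0.0544). Among clusters at or above the median score, an alternative fixed beforehand, the difference was -14.3 points in replicate 1 (exact rotation p = 0.0546), -16.1 points in replicate 2 (exact rotation p = 0.0479) and -18.6 points in the combined list (exact rotation p = 0.0443). When the 2 Mb next to the centromere of each large arm were left out, an alternative added after the data had been seen, the mean difference was -17.9 points (exact rotation p = 0.0136). Those 2 Mb were sparse in the same data, with 14.0% covered against 29.5% of the rest. Leaving them out raises the coverage of the large arms and takes sparse positions out of the rotations, which by itself favours a lower p. Counted as clusters per Mb, chromosome 4 differed by -18.8 as a mean of the replicates (exact rotation p = 0.134). How well reads can be placed on chromosome 4 was not examined.

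**Figure D3:**
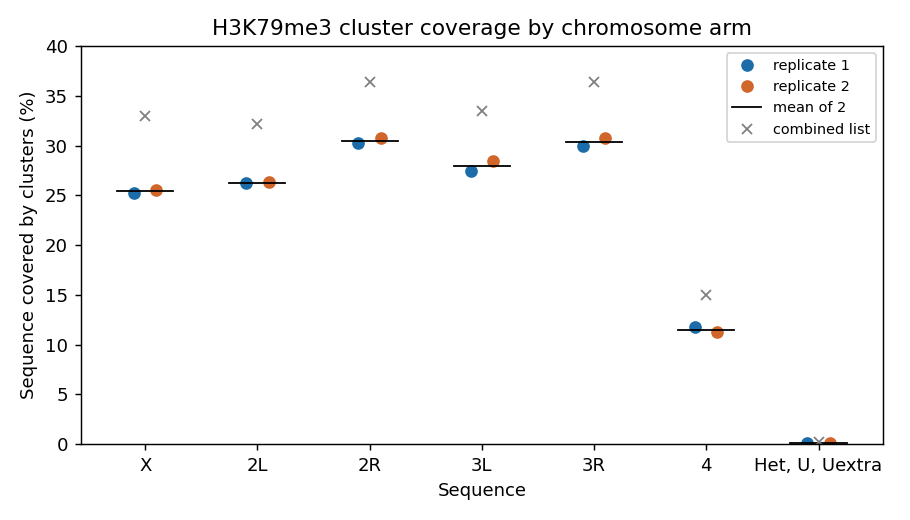
Percentage of each chromosome arm, of chromosome 4, and of the heterochromatic and unplaced sequences (Het, U, Uextra) covered by clusters. Dots are the replicates, lines their mean (n = 2) and crosses the combined list; chromosome 4 lies at 11.8% and 11.2%, below all large arms.

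Clusters were sparse in the 2 Mb at the centromere side of the large arms, except on 3R. Input coverage and how well reads can be placed there were not examined. In the 2 Mb at the centromere side of the 5 large arms, clusters covered 14.0% in both replicates, against 29.1% of the remaining sequence in replicate 1 and 29.8% in replicate 2. The difference of -15.1 points in replicate 1 and -15.8 points in replicate 2 exceeded all 100000 rotations within the arms (two-sided permutation test, p = 1e-05 each, the smallest they can give). As means of the replicates, the 2 Mb held 4.42% on 3L, 10.2% on 2R, 10.5% on 2L and 12.3% on X. The arm 3R was the exception at this distance, with 32.6%. This holds for the end of the arm sequence and not for 3RHet, a separate heterochromatic sequence. Clusters covered 0.331% of 3RHet in replicate 1 and 0.262% in replicate 2. The size of the difference depended on the distance taken. In the 1 Mb next to the centromere it was -21.5 points as a mean of the replicates (permutation p = 1e-05). There 3R held 21.8% and the other large arms between 0.876% and 6.92%, against 29.1% of the remaining sequence. In the 4 Mb next to the centromere it was -7.97 points, with 21.5% against 29.5% (permutation p = 0.0003). The arms then held between 19.58% and 25.03%, the latter on 3R.

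The fourth comparison related the combined list to the lists of the replicates. The combined list took in nearly all of both and added sequence. It had 6943 clusters over 41.2 Mb, and held 99.8% of the covered bases of replicate 1 and 99.8% of those of replicate 2. Of its bases, 74.7% lay in clusters of both replicates, 14.2% in clusters of 1 replicate, and 11.1% (4.58 Mb) in neither. Of its clusters, 4558 overlapped both replicates, 968 overlapped 1, and 1417 (20.4%, 95% Wilson interval 19.5 to 21.4) overlapped neither. These 1417 clusters had a median width of 1323 bases and a median score of 0.405, against 5524.5 bases and 0.831 for clusters overlapping both. Long domains became more frequent, with 300 clusters wider than 20 kb. Of the combined clusters, 936 held at least 2 clusters of replicate 1 and 947 held at least 2 of replicate 2. The narrowest cluster measured 1001 bases in the combined list and 1301 bases in each replicate list.

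The longest domains of the combined list lay on 3L, 3R and 2L, and replicate clusters filled nearly all of each. The longest ran over 118 kb on 3L, from 17923726 to 18041689, and was covered to 99.5% in replicate 1 and 99.4% in replicate 2. The second ran over 106 kb on 3L, from 22295523 to 22401372, 99.5% and 99.9% covered. The third ran over 101 kb on 3R, from 17959614 to 18060738, 98.2% and 96.1% covered. The remaining pair ran over 86.5 kb on 3L, from 5180175 to 5266723 (91.8% and 97.8% covered), and over 84.2 kb on 2L, from 7893488 to 7977659 (98.96% and 98.94% covered). All 5 were split in replicate 1, where they held 3, 2, 5, 8 and 3 clusters in the order given. In replicate 2 they held 4, 1, 3, 5 and 2.

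Among the 10 combined clusters with the highest scores, 8 were also called in both replicates, each covered to over 95% in both. The 8 lay on 3L from 13999552 to 14011611 (score 1.87), on 3R from 20048497 to 20074204 (score 1.85), on 2L from 2979840 to 2990180 (score 1.83) and on 3L from 1798085 to 1805553 (score 1.83). The others lay on 2R from 3269738 to 3277645 (score 1.79), on 3L from 1778963 to 1797941 (score 1.79), on 2R from 9745688 to 9751781 (score 1.76) and on 3L from 20218964 to 20223813 (score 1.75). Both 3L clusters that start at 1778963 and 1798085 are neighbours in the same region. The 2 highest scores of the list, 2.55 on 2L from 21693075 to 21694075 and 2.16 on 3R from 23701454 to 23702454, belonged to clusters of the minimum width of 1001 bases that overlapped no cluster in either replicate.

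Stretches with no cluster in any list reached 505 kb, on 3L from 24025836 to 24530402, 0.0132 Mb from the centromere end of the arm. The next were 438 kb on 3L from 18173921 to 18612192, 5.93 Mb from that end, and 404 kb on 3R from 2485850 to 2890241, 2.49 Mb from the centromere end. The remaining pair were 374 kb on 3L from 23334169 to 23708068 and 362 kb on 2L from 21759789 to 22121344, at 0.835 and 0.890 Mb from the centromere end. Whether reads can be placed in these empty stretches was not examined. Genes in these regions are not named, since the gene table used for names is of FlyBase release 6 and the clusters are on release 5.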

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

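The tests of calling power on X, of minimum-width clusters and of the width limit were chosen or worded after the result had been seen. The bounds of the first and the last were revised after a first version had been run: the test on X then counted any small deficit, and the width limit was first set against 50% of clusters. No biological explanation was tested for any of these patterns, since the design has a single tissue and no second condition.

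Clusters on the heterochromatic and unplaced sequences stand outside the comparisons between arms. Replicate 1 had 37 such clusters and replicate 2 had 28, and 25 of each overlapped one of the other replicate. They covered 0.169% of these sequences in replicate 1 and 0.139% in replicate 2. The long unplaced sequences U and Uextra are part of this total. Coverage was 3.80% and 4.38% on XHet and 1.82% and 1.99% on 2LHet, with 3 clusters on each in both replicates. The unplaced sequence Uextra held no cluster in any of the 3 lists, and whether reads were aligned to it is not given in the sources used here.

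X was less covered than the autosomes in both replicates, without passing the rotation test, so chance is not excluded. Pieces split by gaps shorter than 1000 bases are argued against as the whole source. After joining across such gaps, the covered share on X still differed by -3.13 points in replicate 1 (exact rotation p = 0.207). In replicate 2 it differed by -3.43 points (exact rotation p = 0.224). The median width on X then differed from the autosomal one by -587.5 bases in replicate 1 and -926 bases in replicate 2. Joining widened clusters on X and on the autosomes, and splits by longer gaps were not tested. The sequence next to the centromeres is argued against as the whole source, since the difference was -3.29 points or lower in both replicates without it. Fewer X copies in males may lower the power to call clusters on X, and this stays open: the share of clusters found in the other replicate was lower on X by -1.62 points in replicate 1 and -0.85 points in replicate 2, but in replicate 2 3L lay lower. The share of males among the flies of each library was not examined. X had more clusters per Mb than the autosomes, by 5.26 in replicate 1 (exact rotation p = 0.272). The surplus was 6.54 in replicate 2 (exact rotation p = 0.165) and 7.19 in the combined list (exact rotation p = 0.0993). None of these differences passed the test. These counts do not argue against lower power, which could also split a domain into more clusters. The difference in covered share was -1.67 points in the combined list, against -3.25 in replicate 1 and -3.53 in replicate 2.

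Both highest scores of the combined list belonged to clusters of its minimum width that overlapped no replicate cluster. A spike present only in the combined data is a candidate explanation, and the test left it open. Of 47 minimum-width clusters, 2 (4.26%) overlapped a replicate cluster, against 51 of 681 wider clusters below the minimum width of the replicate lists (7.49%, two-sided Fisher's exact p = 0.568). The replicate lists hold no cluster narrower than 1301 bases, which limits what this comparison can show. Most clusters it covers also lack a high score: 2 of the 47 and 5 of the 681 scored above 1. The median scores were 0.454 and 0.420.

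Of the bases in the combined list, 4.58 Mb lay in neither replicate list. Further reach of clusters seen in a replicate may account for part: 54.6% of these bases lay in combined clusters that touch a replicate cluster. A lower effective threshold may account for others: 96.9% of the clusters overlapping neither replicate scored below the median of the list. Since narrow clusters have low scores, that test separates threshold and width poorly. A lower width limit may also account for some: 47.6% of these clusters (675 of 1417) were narrower than the narrowest replicate cluster, of 1301 bases. It cannot be excluded as the whole cause, since a region can be wider in the combined list than in a replicate. The median width of the 1417 clusters was 1323 bases, close to that limit.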

How the results depend on the processing

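Of 65 alternatives, 35 had a test, and 33 of these kept both direction and side of the threshold. Of the 33, restricting X against the autosomes to the large arms restates the comparison and says nothing about stability, and its 10 kb bins change only the step of the rotation. The exceptions concern X and chromosome 4. X counted as clusters per Mb was 5.90 above the autosomes, the reverse of the covered share, and neither passed the test. Among clusters at or above the median score the mean difference of X was -0.47 points, but its sign also turned in replicate 2 (0.179 points) and in the combined list (0.290 points). Leaving out the sparse 2 Mb next to the centromeres, an alternative chosen after seeing the data, by itself favours a lower p for chromosome 4. Without them, chromosome 4 passed the test, at -17.9 points. With the planned filter of clusters at or above the median score, its mean difference did not pass (-15.2 points, exact rotation p = 0.0501), while replicate 2 (-16.1 points, exact rotation p = 0.0479) and the combined list (-18.6 points, exact rotation p = 0.0443) did and replicate 1 did not (-14.3 points, exact rotation p = 0.0546). Counted as clusters per Mb it did not pass in any list, where the exact rotation p was 0.165 in replicate 1, 0.117 in replicate 2 and 0.232 in the combined list. The cause was not tested in these cases. The difference next to the centromeres passed at every distance tried, from -21.5 points with 1 Mb to -7.97 points with 4 Mb.

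With only clusters at or above the median score of their list, which removes clusters by construction, the mean number per replicate was 3183.5 and the covered length 24.9 Mb. The score correlation between replicates was then 0.86 (0.856) and that of score and width 0.32 (0.316). The narrower range of scores can by itself lower both. In the combined list 16.1% of bases and 12.2% of clusters then lay in neither replicate, and 99.5% of replicate bases lay inside. Joining clusters closer than 1000 bases gave 4553.5 clusters as a mean of the replicates, 34.5 Mb and a correlation of score and width of 0.66 (0.662). The combined list had 6943 clusters and covered 41.2 Mb. Requiring 50% of the cluster or of both clusters left 22.8% and 27.0% of combined clusters overlapping neither replicate. The cause was not tested for these values.

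No paired analysis was possible because the inputs have no list of their own and no test compares groups of samples. The comparisons with start sites and gene lists were not run, for want of an annotation of the same release. The depth is unknown, so its effect on clusters near the threshold cannot be given.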

Other observations

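The score shift between the libraries differed between X and the autosomes, by a test chosen after the values had been seen. Over 1050 paired clusters on X the mean difference, replicate 2 minus replicate 1, was 0.0036, and over 4116 pairs on the autosomal arms it was -0.044 (two-sided exact rotation of cluster order, p = 0.000194, the smallest it can give). The score was higher in replicate 2 for 51.6% of X pairs and 32.4% of autosomal pairs.

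A hypothesis of a random order of clusters and gaps along the arms was set against shuffles of the order of gaps and widths within each arm. The variance of the covered percentage over 1189 windows of 100 kb was 1.19 times the shuffled mean in replicate 1 and 1.19 times in replicate 2. None of 10000 shuffles reached the observed value (permutation p = 0.0001 in each, the smallest they can give). A random order is therefore excluded for both replicate lists. What arrangement raises the variance was not tested, and the low coverage next to the centromeres could contribute.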
